A study of Oncorhynchus mykiss with 16 samples.

How the data were processed

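Gene expression was measured on 16 single-colour microarrays, each hybridised with Cy3-labelled cDNA made from total RNA of rainbow trout head kidney or pyloric ceca. Per the file headers, the slides were scanned at 5 micron, and Agilent Feature Extraction 10.7.3.1 turned each image into spot values with background subtraction, spatial detrending and multiplicative detrending. The processed signal per spot is an intensity on a linear scale, not scaled between arrays, per the file headers. The median foreground and median local background signals deposited for the same spots are also intensities. The authors also deposited a table of 16 columns whose values are a fraction of each array's summed signal. That unit was found from the values, because no header states it: each column was the processed signal of 1 array divided by its sum over the non-control probes, with a coefficient of variation of the ratio of at most 0.000226 over probes, and column sums lay between 1 and 1.00015. The scale of that table was therefore linear, uncentred and without a direction. Its median values per array lay between 2.07e-06 and 7.05e-06. Whether RNA from several fish was pooled on an array is not given in the sources used here.

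The labels put each array in 1 of 4 groups of 4, by tissue and by plasmid, and number the biological replicates in each group 1 to 4. The labels do not say which farm a replicate number stands for, and the spread between arrays was taken as the spread between replicates. All head kidney arrays lay on slide 1 and all pyloric ceca arrays on slide 2, with 1 scan per slide. Slide, scan and tissue cannot be told apart. Within each slide the VP2 arrays lay in row 1 and the empty plasmid arrays in row 2, so position on the slide and plasmid cannot be told apart either. The vaccine comparisons were each made within 1 slide, so a slide term leaves them as they are.

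Processed signals of the 12884 non-control probes were floored at 1, converted to log2, and reduced by the array's 75th percentile over those probes. Control spots were left out, as were 90 spots carrying an outlier mark (0 to 15 per array). No non-control spot was saturated. In the median array 84.9% of the probes were well above background, so the percentile was taken over all of them. A probe was tested if it was well above background on all arrays of at least 1 group, which kept 10782 probes (83.7%). A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom, two-sided), and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 was called. Values per array were compared by exact two-sided permutation tests, whose smallest p with 4 arrays against 4 is 0.0286.

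The files give probe IDs without gene names, and the RefSeq gene table used here (assembly USDA_OmykA_1.1) held none of these IDs, so 0 of 12884 IDs were matched to a gene. Gene lists set out before the data were examined could therefore not be tested. By a rule also fixed then, called probes without annotation are counted and only the 2 with the largest change in each direction are named by ID. To this the requirement was added that a named probe be well above background on all 8 arrays compared, and only 1 copy of a pair is named. Each ID had a partner 6442 numbers further along with nearly the same values, as described with the results. The fit treated the IDs separately, as planned, and their mean was tried as an alternative.

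The fit was tested on data simulated from group means and per-probe spreads of the real arrays, with 200 of 10782 probes changed. Before the change, VP2 groups were given the empty plasmid means of their tissue. For the tissue comparison all groups were given the pyloric ceca empty plasmid means. Each ID was drawn on its own, so copies of a probe did not vary together as on the real arrays. Shifts shared by many probes of an array were not simulated either. The shares that follow hold for such independent draws and may not describe the real arrays. For the head kidney vaccine comparison the fit found 12.4% of probes changed 2-fold, 58.1% of those changed 4-fold and 76.7% of those changed 8-fold. For pyloric ceca the shares were 8.5%, 51.9% and 73.3%. For the tissue comparison they were 9.4%, 56.3% and 76.2%. False calls made up 33.5% of the calls in the head kidney simulation, 4% in the pyloric ceca simulation and 9.5% in the tissue simulation. The simulated arrays kept the larger spread of head kidney, while the fit shares 1 spread between tissues. The real tissue fit called 4634 IDs, far more than the 200 changed here, so the simulated tissue shares do not describe it.

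Alternatives covered the background correction (normexp with offset 50 on the median signals, since mean signals were not used here), scaling, the filter on dim probes, array weights, the prior variance, the replicate number as a block, each tissue fitted alone, a per-probe two-sample test, a looser threshold, the deposited fractions and each array left out in turn. Alternatives chosen after the data were examined are named as such where they are given.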

Results

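The study asked how trout respond to an oral DNA vaccine against infectious pancreatic necrosis virus. The vaccine was a plasmid that carries the gene of VP2, a capsid protein of the virus, behind a cytomegalovirus promoter, packed in alginate microspheres. Fingerlings with a mean weight of 1 g and a mean size of 3.5 cm, kept at 15 °C, came from 4 farms. Each farm's trout were split into subgroups of 6 fish, which were given microspheres with 10 µg of the VP2 plasmid in 10 µl or microspheres with the empty plasmid. At day 7 the head kidney, a main blood-forming and immune organ of bony fish, and the pyloric ceca, blind pouches of the gut behind the stomach, were sampled. Of each tissue and plasmid, 4 arrays were available, 16 in all.

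The arrays differed widely in brightness. The 75th percentile of the processed signal ran from 198.2 to 5883, a ratio of 29.7. In head kidney it was 611.3, 5876, 5883 and 3932 on VP2 replicates 1 to 4 and 1905, 1511, 1914 and 198.2 on the empty plasmid arrays. In pyloric ceca it ran from 1270 to 1955 with VP2 and from 401.3 to 1692 with the empty plasmid. At control probe a22, made for the E1A spike-in RNA of the array system, the log2 signal was 14.5 ± 0.44 (SD, n = 4) on head kidney VP2 arrays and 12.8 ± 0.97 (SD, n = 4) on head kidney empty plasmid arrays (exact permutation test, p = 0.0286, adjusted p = 0.0953 over 10 comparisons of array measures). The share of probes well above background was 82.1 ± 10.5% and 81.4 ± 10.8% (SD, n = 4) in head kidney with VP2 and empty plasmid. In pyloric ceca it was 85.9 ± 4.67% and 73.2 ± 3.93% (SD, n = 4; exact permutation test, p = 0.0286, adjusted p = 0.0953). Negative controls lay at 2.53 to 2.74 (log2) on replicates 1 to 3 of these empty plasmid arrays, against 1.23 to 1.45 with VP2. Replicate 4 lay at 1.37 but was the dimmest array of that tissue. The gap in detection therefore cannot be told apart from background and brightness. The number of arrays limits the precision of every value that follows.

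**Figure D1:**
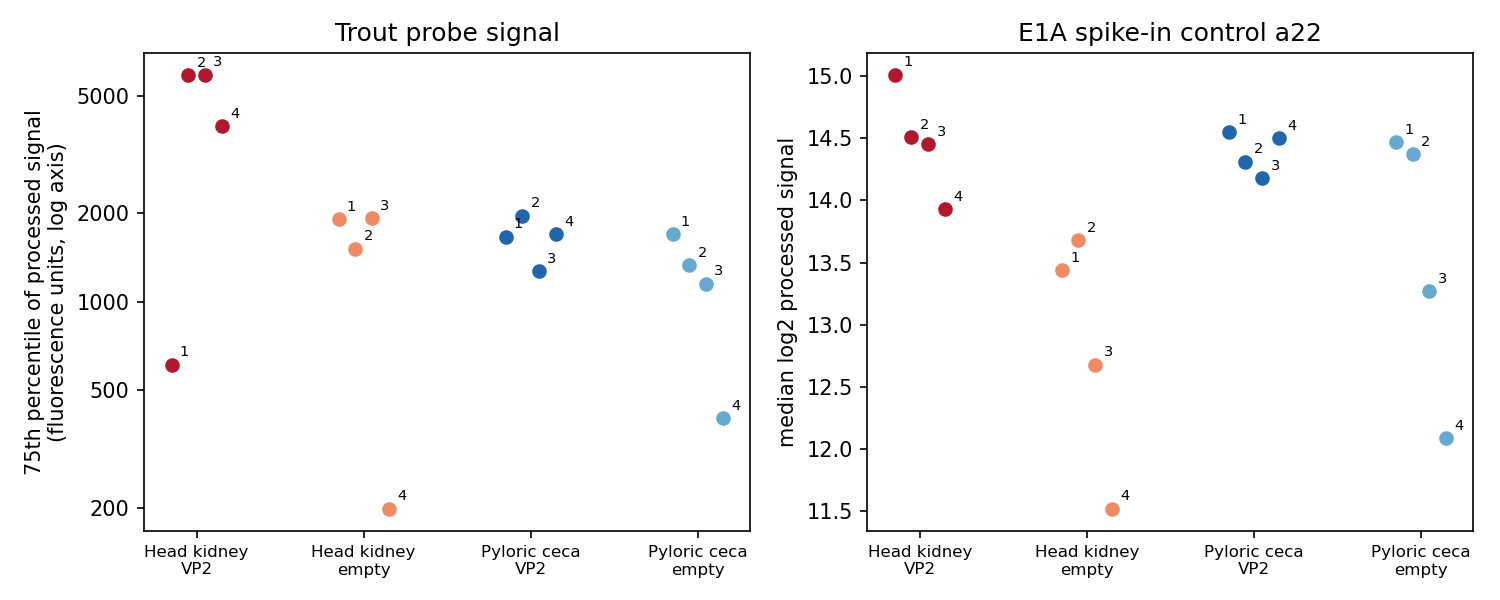
Brightness of each array. The left panel plots the 75th percentile of the processed signal (fluorescence units, log axis) and the right panel the median log2 signal of spike-in probe a22. Each point is 1 array, numbered by replicate, and the dim head kidney arrays are VP2 replicate 1 at 611.3 and empty plasmid replicate 4 at 198.2.

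Most probes were present as a pair of IDs. An ID and the ID 6442 numbers further along correlated at a mean of 0.896 over the 16 arrays, against 0.2 at an offset of 1 and 0.131 at an offset of 100. Among the 5304 pairs with both IDs tested, the median correlation was 0.983 and the mean levels differed by a median of 0.051 on the log2 scale. The 12884 IDs are therefore read here as 6442 probes in 2 copies. The SD of the difference between copies was 1.18 (log2) on head kidney VP2 replicate 4 and between 0.175 and 0.491 on the other 15 arrays. Between arrays of a group the median SD per pair was 0.739 in head kidney and 0.436 in pyloric ceca, several times the median SD between copies of 0.121 and 0.086. Over tested probes, arrays of head kidney correlated at a median of 0.882, those of pyloric ceca at 0.938, and arrays of different tissues at 0.784.

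Head kidney and pyloric ceca differed at a large share of the array. With the empty plasmid, 4634 of 10782 tested IDs (43%) differed between the tissues, 2518 higher in head kidney and 2116 lower (limma, adjusted p under 0.05). The median size of the called differences was 2.1 on the log2 scale, and 4283 called IDs differed more than 2-fold. In 2097 pairs both IDs were called, all in the same direction, and in 378 pairs 1 of the IDs was called. When the copies were averaged, 2316 of 5304 pairs were called, an alternative chosen after the data were examined. With normexp background correction the count was 1349. The share of calls that were higher in head kidney was 54.3%. It was 65% with the deposited fractions, 45.6% with median scaling, and 44.8% with normexp, which changes the background correction and the input signal. Since each tissue lay on its own slide, the difference cannot be told apart from a difference between slides.

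Among probes well above background on all 8 arrays compared, the largest differences were in probes with high signal in the gut. That requirement left out IDs not detected in 1 tissue. For those the bound reached at least 409-fold higher in head kidney and at least 91.9-fold higher in pyloric ceca. JC004389 was 1330-fold lower in head kidney than in pyloric ceca, with normalized log2 levels of -3.76 ± 1.2 and 6.61 ± 0.30 (SD, n = 4; limma, adjusted p = 1.39e-08). JC003868 was 809-fold lower, at -1.39 ± 1.1 against 8.27 ± 0.74 (SD, n = 4; limma, adjusted p = 3.57e-06). Among probes higher in head kidney, JC012797 was 40.2-fold higher, at 1.28 ± 0.85 against -4.05 ± 0.46 (SD, n = 4; limma, adjusted p = 0.000321). JC006774 was 36.3-fold higher, at 2.79 ± 0.31 against -2.39 ± 0.39 (SD, n = 4; limma, adjusted p = 9.11e-07). On single empty plasmid arrays JC012797 fell to 0.026 in head kidney and JC004389 reached 7.06 in pyloric ceca. The second copies of these probes differed by -10.3, -9.42, 5.16 and 5.15 on the log2 scale. With normexp the folds of the named probes were smaller, 428 for JC004389, 512 for JC003868, 11.5 for JC012797 and 18.6 for JC006774, with the same directions. The files do not pair these IDs with genes.

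Some IDs were well above background on the empty plasmid arrays of 1 tissue only. On the empty plasmid arrays, 202 IDs were well above background on all 4 head kidney arrays and on no pyloric ceca array, and 187 of them were called. The bound on the difference was over 1 for 200 of the 202 IDs, with a median over those 200 of at least 3.29-fold and a highest of at least 409-fold. The reverse held for 22 IDs, all called, at a median of at least 6.11-fold and up to at least 91.9-fold. Each bound sets the mean of the bright group against the lowest signal well above background on each array of the dim group, or the probe's own signal where that was higher. Detection was lower on the pyloric ceca empty plasmid arrays in general, at 73.2%, against 81.4% in head kidney. With VP2 it was 85.9% in pyloric ceca. Negative controls lay at 2.53 to 2.74 (log2) on replicates 1 to 3 of those arrays and at 1.24 to 1.76 in head kidney with the empty plasmid. The 202 against 22 IDs therefore cannot be read as presence in 1 tissue alone.

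Tissue differences were grouped along the order of the IDs. Runs of neighbouring pairs were found after the data were examined. They came from the running median over 21 pairs of the tissue difference on all 16 arrays. Stretches beyond 1.5 (log2) counted from 15 pairs on and were joined across gaps of up to 30 pairs. In 1000 shuffles of the order no run was longer than 16 pairs. The longest run held 887 pairs, numbers 770 to 1656, of which 609 pairs had both IDs tested. Of its 1275 tested IDs, 1046 were called higher in head kidney and 20 lower. Its median level was -2.19 ± 1.11 in head kidney and -4.98 ± 1.25 in pyloric ceca with the empty plasmid (SD, n = 4), a difference of 2.79 or 6.92-fold (exact permutation test, p = 0.0571). The run lay low in signal in pyloric ceca, and an ID could pass the filter through head kidney alone. The fold and the 1046 against 20 IDs may therefore depend on background and filter, which was not tested. A run of 153 pairs, numbers 2042 to 2194, was 7.21-fold lower in head kidney, at -1.32 ± 0.73 against 1.53 ± 0.23 (SD, n = 4; exact permutation test, p = 0.0286). A run of 17 pairs, numbers 308 to 324, was 5.03-fold higher in head kidney, at 0.43 ± 0.78 against -1.90 ± 0.51 (SD, n = 4; exact permutation test, p = 0.0286). These runs were picked for their tissue difference, so the p-values describe them and are not independent tests.

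**Figure D2:**
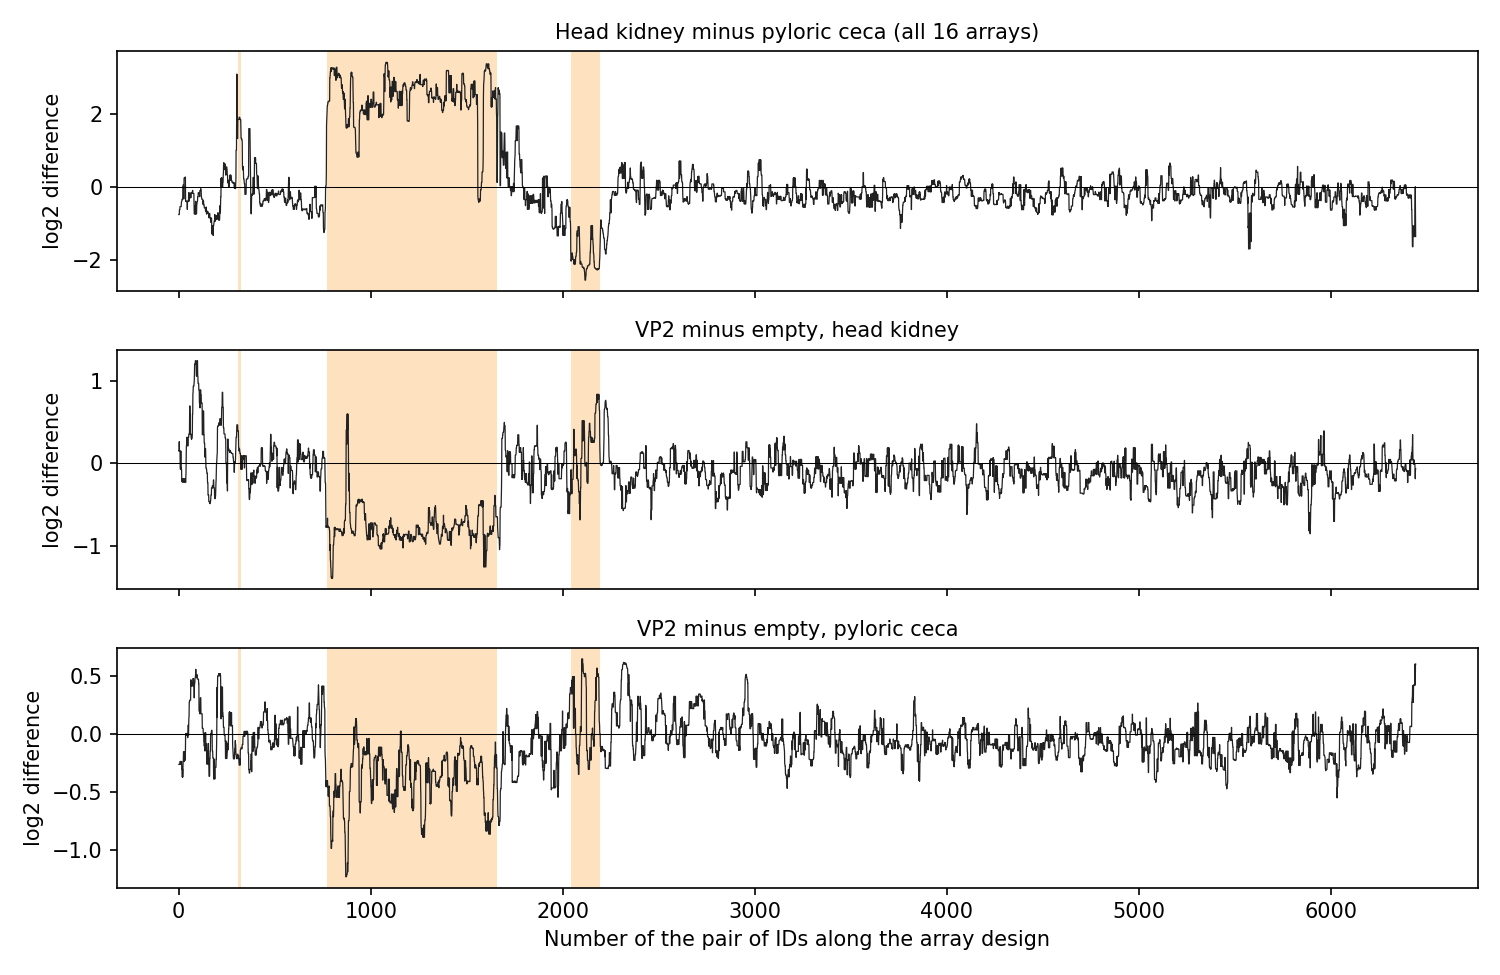
Expression differences along the order of the 6442 pairs of IDs. Each line is a running median over 21 pairs of a log2 difference. The top panel gives the difference between tissues on all 16 arrays. The others give VP2 against empty plasmid in head kidney (middle) and in pyloric ceca (bottom), and shading marks the 3 runs. In the run from 770 to 1656 the tissue difference lies mostly above 1.5, and the VP2 line lies mostly below 0 in both tissues.

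In head kidney no probe passed the test for a difference between the VP2 vaccine and the empty plasmid. Of 10782 IDs 0 were called (limma, lowest adjusted p = 0.184), and a per-probe two-sample test on the same values with Benjamini-Hochberg adjustment also called 0. At an unadjusted p under 0.05 there were 1277 IDs, 422 higher and 855 lower with VP2, where 539 would be expected by chance, and the two-sample test gave 543. The median standard error was 0.449 on the log2 scale in this fit, which shares 1 spread between tissues. A typical 95% interval thus reached 0.96 to either side, a 1.94-fold change. Head kidney fitted alone had a larger median standard error of 0.519, so that interval is likely too narrow for this tissue. Its own fit gave 595 IDs at an unadjusted p under 0.05 and 0 calls. The estimated difference was over 2-fold for 2081 IDs, and none of these was called. The median difference was -0.55 (log2) in the tenth of probes with the lowest signal and -0.08 in the tenth with the highest.

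The head kidney count changed when single arrays were left out. Without VP2 replicate 1, a dim array, 353 of 11351 IDs were called, 306 lower with VP2 and 47 higher, while the head kidney arrays fitted alone without it gave 0 calls, an alternative chosen after the data were examined. Without empty plasmid replicate 4, the dimmest array, there were 0 calls, and the IDs at an unadjusted p under 0.05 went from 1277 to 602. With normexp on all arrays there were 193 such IDs. Without empty plasmid replicate 3 there were 9 calls, all lower. Array weights, which gave VP2 replicate 1 a weight of 0.221, called 72 IDs, 68 of them lower. The run from 770 to 1656 lay at -3.08 ± 1.11 with VP2 and -2.19 ± 1.11 with the empty plasmid (SD, n = 4), a difference of -0.90 that did not pass a test without pairing (exact permutation test, p = 0.286, adjusted p = 0.572 over 6 comparisons of runs). The run from 2042 to 2194 differed by 0.66 (exact permutation test, p = 0.286, adjusted p = 0.572) and that from 308 to 324 by -0.20 (exact permutation test, p = 0.886, adjusted p = 0.886).

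**Figure D3:**
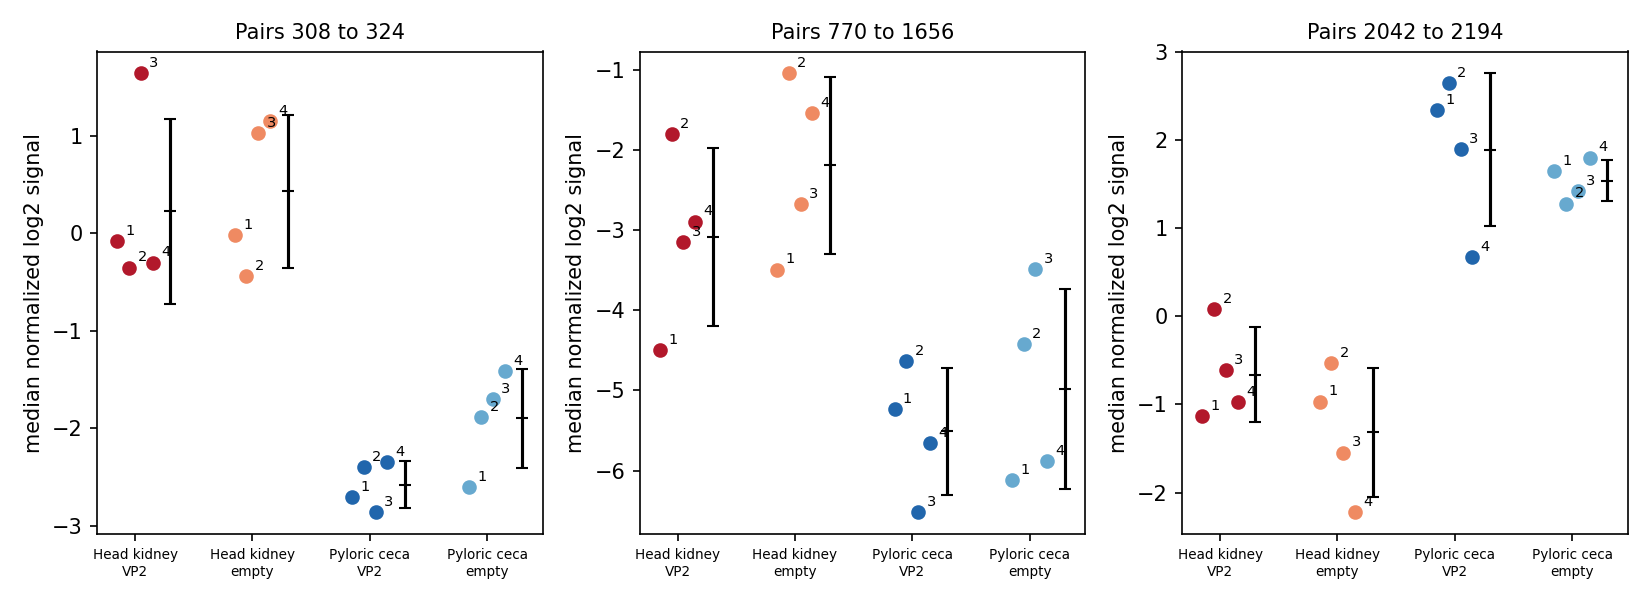
Median normalized log2 signal of 3 runs of neighbouring pairs on each array. Points are arrays numbered by replicate, and bars give the mean and SD of the 4 arrays of a group. In the middle panel the VP2 and empty plasmid arrays of head kidney overlap, with means of -3.08 and -2.19.

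In pyloric ceca 0 of 10782 IDs were called (limma, lowest adjusted p = 0.996). At an unadjusted p under 0.05 there were 402 IDs, 231 higher and 171 lower with VP2, fewer than the 539 expected by chance. Fitted alone, with its smaller spread, this tissue gave 1027 such IDs and 0 calls, and the per-probe two-sample test gave 1085 and 0 calls. Its median standard error fell to 0.312 in that fit, against 0.519 for head kidney alone. Differences over 2-fold were estimated for 806 IDs, none of them called. Array weights called 85 IDs, 51 lower and 34 higher. The run from 770 to 1656 lay at -5.51 ± 0.79 with VP2 and -4.98 ± 1.25 with the empty plasmid (SD, n = 4; exact permutation test, p = 0.514, adjusted p = 0.617). The other runs differed by 0.35 for 2042 to 2194 (exact permutation test, p = 0.457, adjusted p = 0.617) and -0.68 for 308 to 324 (exact permutation test, p = 0.0857, adjusted p = 0.514).

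The vaccine's effect was compared between the tissues directly. For the difference of the effects, 0 of 10782 IDs were called (limma, lowest adjusted p = 1), and 377 IDs had an unadjusted p under 0.05, 90 higher and 287 lower in head kidney relative to pyloric ceca. The interval of this difference was wider, with a median standard error of 0.636. Across probes the effects in head kidney and pyloric ceca correlated at r = 0.364, and 64.5% of IDs had the same sign in both. Outside the run from 770 to 1656 the correlation was 0.293. Probes are not independent replicates, and random regroupings of the arrays reached correlations of up to 0.518, 12 of 100 regroupings being as large in size as the observed value with the real one included.

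**Figure D4:**
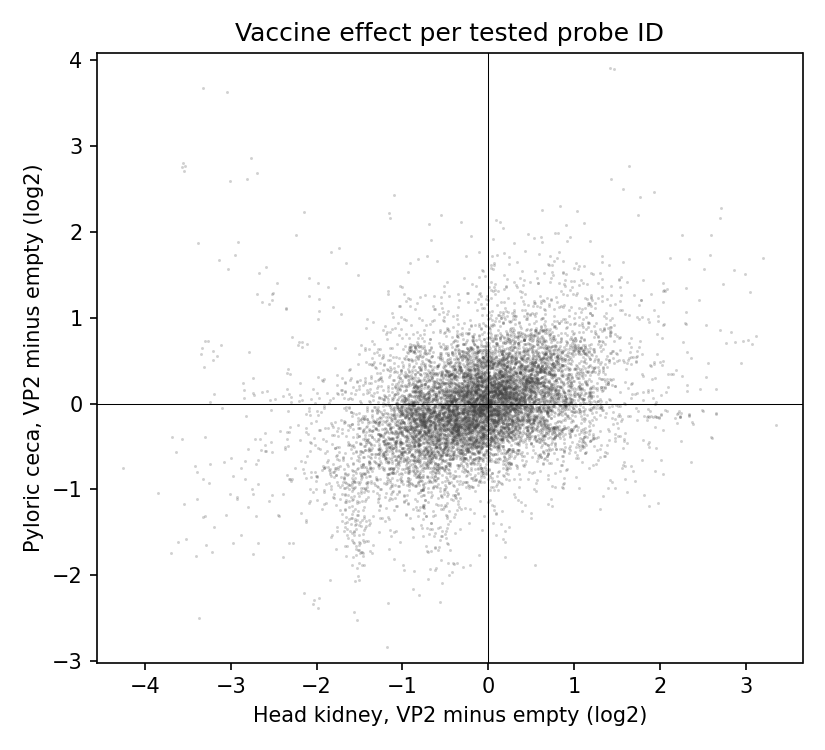
Difference between VP2 vaccine and empty plasmid in head kidney (horizontal axis, log2) and in pyloric ceca (vertical axis, log2). Each point is 1 of 10782 tested IDs, and the correlation across IDs is 0.364 while no ID was called in either tissue.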

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

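Leaving out each array in turn and the regroupings for the correlation between tissues were planned, and the other tests in this part were chosen after the results were seen. In 52 groups of 4 arrays tested for a value far from the others, 8 stood apart, where chance gives about 1 in 20. In head kidney the empty plasmid replicate 4 had a log2 75th percentile of 7.63, against 10.6 to 10.9 on the other 3 arrays, and 65.3% of its probes were well above background, against 85.2 to 88%. On head kidney VP2 replicate 1 the log2 difference between trout and spike-in signal was -5.76, against -1.99 to -1.93 on the others. The negative controls of pyloric ceca empty plasmid replicate 4 lay at 1.37 (log2), against 2.53 to 2.74. On the VP2 arrays of the same slide they lay at 1.23 to 1.45, so replicates 1 to 3 of the empty plasmid were the raised ones on that slide. The run of pairs 308 to 324 lay at 1.64 on head kidney VP2 replicate 3, against -0.35 to -0.08. JC012797 lay at 3.58 on head kidney VP2 replicate 3, against 0.63 to 1.09, and at 0.026 on head kidney empty plasmid replicate 3, against 1.56 to 1.83. JC004389 lay at 7.06 on pyloric ceca empty plasmid replicate 4, against 6.41 to 6.5. Outside the trout probes, 3 of 25 control probes named ETG or RC were well above background on at least 8 arrays, while at most 6.49% of negative control spots were on any array.

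Leaving out the dim VP2 replicate 1 took the head kidney vaccine count from 0 to 353, and the vaccine itself is the biological explanation that the design offers. Of the 35 splits of the remaining 7 arrays into 3 and 4, 2 gave as many calls with the real one included, and the highest other gave 594, so chance could not be excluded. A bent signal scale between bright and dim arrays may account for part of the calls: cyclic loess left 280, while normexp background correction left 0, and which of these is closer to the truth was not settled. The head kidney arrays alone gave 0 calls and 1494 IDs at an unadjusted p under 0.05, against 2465 in the shared fit, which is consistent with a spread set too low for head kidney by the quieter pyloric ceca, though fewer arrays also lower the count. Without VP2 replicate 1, the head kidney VP2 arrays had 75th percentile signals of 5876, 5883 and 3932. All lay above the empty plasmid arrays, at 1905, 1511, 1914 and 198.2. Probes were also put in 10 bins from lowest to highest signal. The 353 calls fell in these as 61, 64, 50, 72, 26, 21, 14, 23, 9 and 13. For 224 of the 353 calls both IDs of the pair were called. The vaccine stays open as an explanation that these arrays neither exclude nor separate from brightness or the position on the slide.

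The level of the run of pairs 770 to 1656 varied between arrays of 1 group by more than the vaccine difference. Its deviations from the group means correlated with array brightness at Pearson r = 0.22 (95% interval -0.31 to 0.65, permutation p = 0.41, adjusted p = 0.41; Spearman rho = 0.121, permutation p = 0.66; r = 0.192 without the 2 most extreme arrays). Against trout signal minus spike-in, r was 0.317 (95% interval -0.21 to 0.7, permutation p = 0.24, adjusted p = 0.41; Spearman rho = 0.176, permutation p = 0.51; r = 0.135 without 2 arrays). Both intervals are those for 16 independent values, while the deviations were taken from 4 group means, so they are somewhat too narrow. The 16 arrays thus leave brightness open. The pairs of the run moved together, with a mean pairwise r of 0.604 against at most 0.056 in 100 random sets of pairs. Probes that detect a set of related transcripts could give this. The run was picked for a shared behaviour and lay low in signal, so the comparison cannot tell related transcripts from another shared shift. Replicate 2 was above the group mean in all 4 groups, by 0.964 (log2) on average, and replicate 1 averaged -0.895 but lay above the mean in pyloric ceca with VP2. Fish of 1 origin behind a replicate number are a possible explanation, but an exact permutation of the numbers within groups (13824 arrangements) gave p = 0.102, and the labels do not tie the numbers to farms.

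On head kidney VP2 replicate 4, 8.47% of tested pairs differed more than 2-fold between copies, against 0.189 to 5.06% on the other 15 arrays. For 1053 pairs with 1 copy inside rows 65 to 128 and columns 28 to 55 of the array, the copy inside differed by a median of -0.65 (log2) from the copy outside on this array, while the lowest of the other arrays was 0.042. With both copies outside that area only 1.85% of pairs differed more than 2-fold, against 32% with 1 copy inside, which argues against noise over the whole array. The values are consistent with a local defect of the array surface. No biological explanation was tested.

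The counts were also set against other splits of the arrays. The vaccine counts of 0 are reached by any split (35 of 35 in head kidney, 35 of 35 in pyloric ceca and 100 of 100 regroupings for the difference), so the splits say nothing about them. The highest counts in other splits were 664, 7 and 6. At an unadjusted p under 0.05, 9 of the 35 splits of head kidney gave at least 1277 IDs (highest other 2678), 6 of the 35 of pyloric ceca at least 402 (highest other 1149), and 49 of 100 regroupings at least 377 for the difference (highest other 2094). For the correlation it was 12 of 100 (highest other 0.518). Chance was not excluded for these counts at an unadjusted p or for the correlation. For the tissues 1 of 35 splits, the real one, reached 4634 calls (highest other 1) or 5391 IDs (highest other 2926). The real split thus stood above every other. A share of 1 in 35 is the lowest these splits can give, and the other splits mix the tissues within a group, so they cannot exclude chance.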

How the results depend on the processing

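The vaccine counts of 0 in both tissues, and of 0 for their difference, held under every planned background, scaling, filter, prior variance and block setting run (each tissue alone and the per-probe test give no value for the difference). They did not hold under the looser threshold of an unadjusted p under 0.05 and 1.5-fold, with 1245 in head kidney, 383 in pyloric ceca and 377 for the difference, which follow from the threshold itself. Array weights gave 72 and 85, and the cause was not tested. Leaving out each array in turn gave 0 to 353 in head kidney, 0 in pyloric ceca and 0 for the difference. Among alternatives chosen after the data were examined, leaving out the 3 dimmest arrays gave 254 in head kidney and 13 for the difference. Without the dim VP2 array, head kidney counts were 175 with quantile normalization, 280 with cyclic loess, 0 with normexp, 273 over probes well above background on all arrays, 215 by pair means and 0 in head kidney alone, and 170 without VP2 array 4 as well.

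The tissue count of 4634 was between 3782 and 5400 with each array left out, 1349 with normexp, 2998 over the 6877 probes well above background on all 16 arrays (fewer probes tested) and 2316 by pair means (fewer rows tested); the cause of the normexp value was not tested. The correlation of 0.364 between tissues was 0.25 to 0.401 with each array left out, 0.447 with normexp, 0.328 with no filter on dim probes, 0.276 with array weights and 0.27 without the 3 dimmest arrays; the cause was not tested. The 4 named probes, picked for their large differences, kept direction and call in all 130 values computed. Many of the settings, such as leaving out a VP2 array, cannot change the estimated tissue difference, so there the direction was fixed. Scaling moved the median tissue difference of all tested probes from -0.0024 to between -0.25 and 0.23, the median head kidney vaccine difference from -0.11 to between -0.16 and 0.33, and that of pyloric ceca from -0.033 to between -0.063 and 0.16. With normexp, which changes the background correction and the input signal, these medians were -0.1, -0.19 and -0.49.

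With a replicate block the counts were 0, 0, 0 and 3967, and with the number as a random effect 0, 0, 0 and 4781 at a consensus correlation of 0.0571. Same-numbered head kidney arrays had correlated deviations of 0.32, 0.41, 0.25 and -0.042, and pyloric ceca arrays 0.14, 0.38, -0.49 and -0.19, so some same-numbered arrays deviated in opposite directions, and the arrays share only a number. Within numbers, the run of pairs 770 to 1656 differed by -1, -0.76, -0.48 and -1.35 between VP2 and empty plasmid in head kidney (exact sign-flip permutation, p = 0.125, the smallest 4 pairs allow) and by 0.89, -0.21, -3.03 and 0.23 in pyloric ceca (exact permutation p = 0.875), added after the data were examined. The slide as a block and the mean over probes of a gene were not run, the first because each slide held 1 tissue and the second for want of gene names; the 2 gene list results were not run for the same want. On the dimmest array 65.3% of probes were well above background.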

Other observations

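The tests in this part were chosen after the data were examined. The longest stretch of pairs that lay higher with VP2 in head kidney held 34 pairs from number 74 on, with a running median above 0.75 (log2). Its level was 0.035 ± 1.41 with VP2 and -1.05 ± 1.06 with the empty plasmid in head kidney (SD, n = 4; difference 1.09, exact permutation test, p = 0.257). In pyloric ceca it was -0.27 ± 1.30 and -0.98 ± 1.67 (SD, n = 4; difference 0.72, exact permutation test, p = 0.571). Without VP2 replicate 4 of each tissue the differences were 0.53 and 0.35. The stretch was picked for its difference in head kidney, and the arrays of each group overlapped in both tissues.

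The spike-in probe E1A_r60_3 went with the brightness of the trout probes. On head kidney VP2 replicate 1 it lay at 6.29 (log2), where spike-in probe a22 lay at 15.01. Its log2 signal ran from 5.74 to 11.4 over the 16 arrays and correlated with the log2 75th percentile of trout signal at Pearson r = 0.906 (permutation p = 1e-05, the smallest the resampling can give) and Spearman rho = 0.868 (permutation p = 2e-05). Without the 2 arrays farthest from the median brightness r was 0.959. Within the slide of head kidney r was 0.97, between 0.96 and 0.991 with 1 array left out. Within that of pyloric ceca r was 0.393, and it was 0.831 without empty plasmid replicate 4, the array that moved it most.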
